A study of Mus musculus with 13 samples.

How the data were processed

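Genomic DNA was measured by hybrid capture sequencing with a mouse version of a 578-gene cancer panel. Of 13 samples, 4 were labelled KC_WT, 4 KC_KO and 3 cultured KPC cells, and the others were tail DNA of a C57BL/6 mouse and a pooled normal. Per the labels' protocols, libraries were built from 89 to 100 ng of DNA with 8 PCR cycles, average coverage was 576 and 99% of targets had at least 30-fold coverage. Samples were grouped by their titles, and each row of the table was tied to a library by its sample name. The pooled normal was not analysed here.

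The authors deposited a table of variant calls with 1 row per variant and library. It gave counts of total, reference and variant reads in the tumour library and in matched tail DNA, and the variant allele fraction, which the authors deposited as a fraction equal to variant reads over depth. Per the submitters' processing notes, the tools were cutadapt 1.6, BWA 0.7.12, Picard and GATK 3.2, and the genome build was hg19, a human build. Coordinates are printed as deposited, without a named mouse build; all 31 variants lay within the gene of the same name in the GRCm38.p6 annotation. Per the file headers and columns, 62 rows came from MuTect, 45 were MuTect rows marked as rescued and 7 came from HaplotypeCaller. The authors' rule for listing a row is not given in the sources used here. Rescued rows had at least 4 variant reads and a fraction of at least 1.02%. A variant without a row in a library has no read counts there, so absence means only that no row was listed; how many reads a row needed is not known. Capture, PCR and the callers' filters can each move an allele fraction, and insertions next to exon ends depend on alignment.

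A call was a row with a depth of at least 20 reads, at least 5 variant reads and a fraction of at least 0.05. This left 48 rows below the minimum. Values per library were compared with exact two-sided permutation tests of the difference of means, over 70 arrangements for 4 against 4 libraries and 165 for 8 against 3. The smallest p they allow is 0.0286 and 0.00606. The design had planned a test of allele fractions over all called variants. Since reads were given only for listed rows, the stated fallback was used: presence was tested with Fisher's exact test per variant (two-sided), and fractions only for the 5 variants called in all libraries. These were tested with limma 3.58.1 in R 4.3.3 on log2 of variant reads plus 0.5 over reference reads plus 0.5, with all 3 groups in one fit. P-values were adjusted by the Benjamini-Hochberg method at 0.05 within each family. At 4 against 4 libraries, a single result cannot pass after exact permutation adjusted over 5 variants, 6 substitution classes or 8 gene lists, so counts at an unadjusted p are given too. With so few variants, the shared estimate of variance in limma rests on 5 values. The limma step was tested on 200 simulated sets of 5 variants with known changes in odds. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

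Intervals of single fractions are exact Clopper-Pearson intervals at 95%, and the limit for 0 reads is 3 counts over the depth. Median depth over the 5 shared sites was 469 to 683 reads per library, so a fraction near 20% carries an interval of several percentage points. Replicate libraries were compared by chi-square over these sites. At 0.05 it separated 0 of 3 pairs of cultured libraries, 6 of 6 KC_WT pairs and 3 of 6 KC_KO pairs. Depths differed between all cultured libraries, so each was kept as a library; they may be repeat measurements of 1 culture.

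Named variants followed a rule fixed before the data were examined. It took the label alleles of Kras and Trp53, variants past the threshold of a contrast or the 5 with the smallest p, and every call in a fixed list of pancreatic cancer drivers. It also took up to 15 variants called in all libraries, up to 10 called in at least 2 libraries of one liver group and none of the other, and up to 10 called in at least 3 liver libraries and no cultured library. The 8 gene lists were pancreatic cancer drivers, RAS, MAPK and PI3K signalling, DNA repair, chromatin regulators, antigen presentation with interferon and immune recognition, WNT with NOTCH, TGF-beta and adhesion, cell cycle and apoptosis, and macrophage and Kupffer cell factors. Alternatives were a depth minimum of 100, no fraction minimum or 0.10, removal of variants with a tail fraction of at least 0.02, single base variants alone, other models for fractions, 1 read added, a replicate block and each library left out in turn. For shared and private variants, presence at 2 or more variant reads was a further alternative. Use of all listed rows, fractions divided by that of Trp53 R172H and rank permutation were added after the data were seen.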

Results

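DNA of a mouse pancreatic cancer cell line, KPC, was sequenced over a capture panel of 578 cancer genes. The line carries a G12D allele of Kras and an R172H allele of Trp53, per the labels. Tumour cells had been sorted from livers 2 weeks after injection and fell into a group of 4 labelled KC_WT and a group of 4 labelled KC_KO. The labels do not spell out KC, and the series title concerns Kupffer cells, the resident macrophages of the liver. The design text names hosts with and without a Clec4f Cre driver and does not say which label goes with which. The other libraries were 3 of the cultured line, here called cultured cells, and mouse tail DNA, which gave the background at each variant site. A pooled normal sample was not analysed here. The table listed 114 rows, each a variant in 1 library, for 31 distinct variants in 28 genes, all of them changing the protein. Depth was 6 to 1462 reads per row, with a median of 493.5, and 224 to 1462 reads at the 5 sites listed in all 11 tumour cell libraries. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

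Both engineered alleles were read in all 11 tumour cell libraries. Trp53 R172H, a hotspot change in the p53 tumour suppressor, lay at chromosome 11, position 69588512, in exon 5 of 11. It made up 99.8% ± 0.0109 of reads in cultured cells (SD, n = 3), 95.2% ± 2.96 in KC_WT (SD, n = 4) and 92.2% ± 9.90 in KC_KO (SD, n = 4). Kras G12D, an activating change in the RAS family GTPase, lay at chromosome 6, position 145246771, in exon 2 of 5. It made up 50.6% ± 4.0 of reads in cultured cells (SD, n = 3), 51.7% ± 3.37 in KC_WT (SD, n = 4) and 49.9% ± 8.31 in KC_KO (SD, n = 4). Tail DNA had 1 variant read of 552 at the Trp53 site, and 0 of 299 at the Kras site, which allows a share of up to 1.0%. The fractions of KC_KO replicate 4 were the lowest of the 11 libraries for both alleles, 77.4% for Trp53 R172H (interval 73.5 to 81.0) and 37.8% for Kras G12D (interval 31.7 to 44.2). The difference between KC_KO and KC_WT was -2.96 percentage points for Trp53 R172H and -1.78 for Kras G12D, neither past the threshold (exact two-sided permutation p = 0.800 and 0.857). Without KC_KO replicate 4 both differences turned, to 1.97 and 2.26 points.

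The number of variants per tumour was compared between KC_KO and KC_WT to ask whether tumour cells from the 2 kinds of host carried different mutation loads. A call required at least 20 reads, 5 variant reads and a variant allele fraction of 5%, which 66 of the 114 rows met, for 12 distinct variants in 11 genes. KC_WT libraries held 5, 5, 6 and 8 calls, a mean of 6.00 ± 1.41 (SD, n = 4). KC_KO libraries held 5, 5, 6 and 11 calls, a mean of 6.75 ± 2.87 (SD, n = 4). The difference of 0.75 calls was smaller than the spread between replicates (exact two-sided permutation p = 0.886, where the smallest p the design allows is 0.0286). KC_KO replicate 4 supplied the direction: without it the difference was -0.667 calls (exact permutation p = 0.714). Every listed row changed the protein, so protein-altering calls gave identical values by construction, and silent changes do not enter these counts. With single base substitutions alone the difference was 0, and with all listed rows, a comparison added after the data were seen, it was 2 rows (exact permutation p = 0.457).

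Of the 12 called variants, 5 were called in all 11 libraries: Trp53 R172H, Kras G12D, Fgfr2 F664L, Erbb3 S844C and Tet2 H801R. Fgfr2 and Erbb3 encode receptors of the fibroblast growth factor and ERBB families, and Tet2 encodes a dioxygenase that oxidises 5-methylcytosine. Fgfr2 F664L lay at chromosome 7, position 130172870, in exon 14 of 18, and made up 19.5% ± 1.18 of reads in cultured cells (SD, n = 3), 20.6% ± 2.53 in KC_WT (SD, n = 4) and 20.7% ± 1.70 in KC_KO (SD, n = 4). Erbb3 S844C lay at chromosome 10, position 128572514, in exon 21 of 28, with 16.4% ± 1.19 in cultured cells (SD, n = 3), 19.0% ± 1.80 in KC_WT (SD, n = 4) and 17.3% ± 2.22 in KC_KO (SD, n = 4). Tet2 H801R lay at chromosome 3, position 133486270, in exon 3 of 11, with 12.9% ± 0.871 in cultured cells (SD, n = 3), 15.4% ± 2.28 in KC_WT (SD, n = 4) and 13.7% ± 1.54 in KC_KO (SD, n = 4). Tail DNA had 0 variant reads of 509 at the Fgfr2 site, 1 of 667 at the Erbb3 site and 2 of 889 at the Tet2 site.

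**Figure D1:**
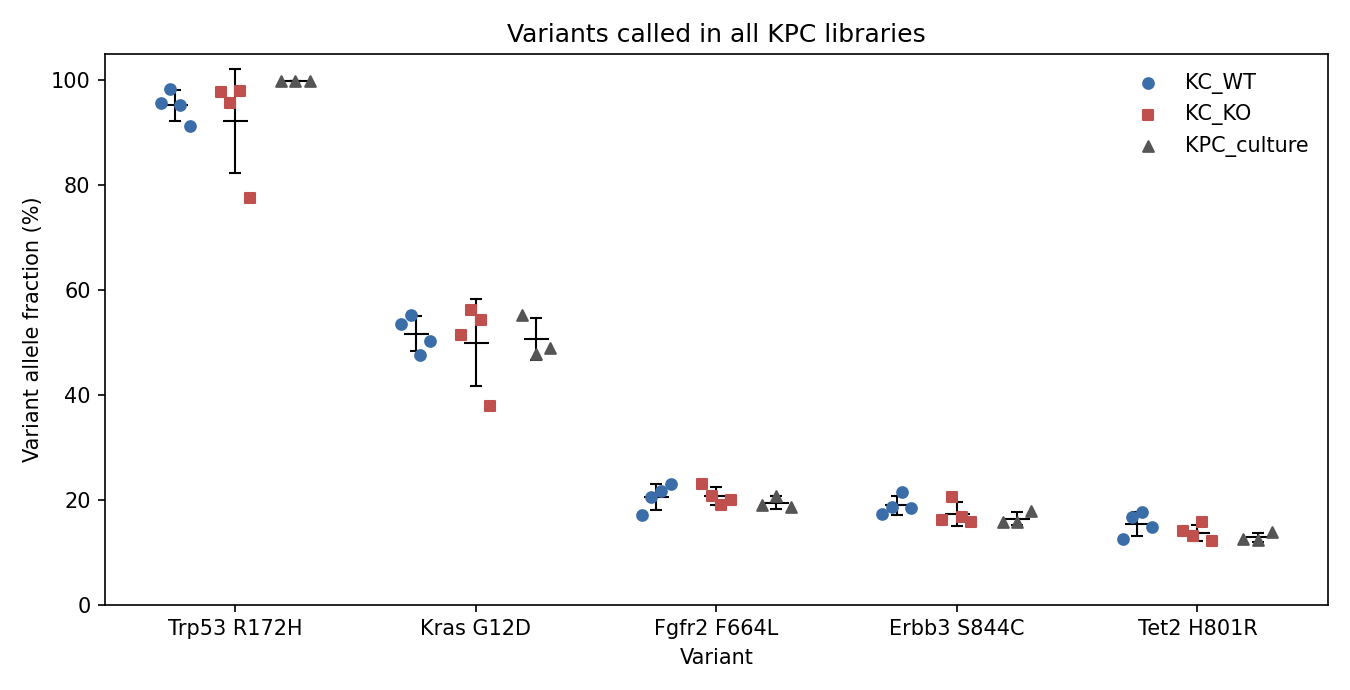
Variant allele fraction in percent (vertical axis) of the 5 variants called in all 11 libraries (horizontal axis), with 1 point per library, horizontal bars for the group means and error bars of 1 SD (4 KC_WT, 4 KC_KO and 3 cultured libraries). The lowest Trp53 R172H and Kras G12D points, 77.4% and 37.8%, are both KC_KO replicate 4.

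None of these 5 variants passed the test for a different allele fraction in KC_KO and KC_WT. In limma on the log2 odds of variant to reference reads, 0 of 5 passed an adjusted p of 0.05 and 0 of 5 an unadjusted p of 0.05. The log2 odds of KC_KO over KC_WT were -0.19 ± 0.14 for Tet2 H801R (SE), -0.17 ± 0.13 for Erbb3 S844C, -0.16 ± 0.89 for Trp53 R172H, -0.11 ± 0.23 for Kras G12D and 0.013 ± 0.13 for Fgfr2 F664L, with a lowest limma adjusted p of 0.587. A quasi-binomial model also gave 0 of 5, as did exact permutation, in which fewer than 3 variants could not pass after adjustment. In simulated data of this size, 65.0% of 1.5-fold and 97.8% of 2-fold changes in odds were called. All simulated variants had the same library-to-library spread, below that of Trp53 R172H here. The SE here ran from 0.13 to 0.89 and was 0.23 for Kras G12D, so these rates do not carry over to each variant. The median allele fraction over the calls of a library was 19.0% ± 2.41 in KC_WT (SD, n = 4) and 19.9% ± 2.51 in KC_KO (SD, n = 4), a difference of 0.840 points (exact permutation p = 0.600), which was -0.205 without KC_KO replicate 1.

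Tumour cells from liver were set against the cultured line to ask what differed after growth in the host. Reference reads at the Trp53 R172H site were nearly lacking in cultured cells, with 2 of 1706 reads (0.117%), and made up 266 of 4439 reads (5.99%) over the 8 liver libraries. Each of the 8 liver libraries had a higher reference share, 1.6% to 22.4%, than any cultured library, 0% to 0.186%, a separation that chance gives in 1.21% of arrangements (exact two-sided permutation of ranks, p = 0.0121). The pooled ratio was 51.1 (interval 14.0 to 424, counting error only) and 33.4 without KC_KO replicate 4 (interval 9.08 to 278). Trp53 R172H was the only 1 of the 5 shared variants to pass in limma, where its log2 odds fell by 4.61 ± 0.857 (SE) in liver against culture (limma adjusted p = 0.00189). The size of that change depends on the 0.5 reads added to each count. Whether the reference reads came from tumour cells or from host cells among the sorted cells was not tested. The fall in odds is therefore not read as a change of the tumour allele. The call was lost with limma on the arcsine scale (adjusted p = 0.0951), a quasi-binomial model (0.465) and exact permutation of the fractions (0.354). In the quasi-binomial model the log2 odds were -5.76 ± 5.77 (SE), a change no smaller but with a wide error. Log2 odds of liver over culture were 0.20 ± 0.14 (SE) for Tet2 H801R, 0.17 ± 0.13 for Erbb3 S844C, 0.10 ± 0.12 for Fgfr2 F664L and 0.010 ± 0.22 for Kras G12D, none past the threshold.

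Calls per library averaged 6.38 ± 2.13 in liver (SD, n = 8) and 5 in each of the 3 cultured libraries. The difference of 1.38 calls was smaller than the spread between liver libraries (exact two-sided permutation p = 0.485). With each library left out in turn it ranged from 0.714, without KC_KO replicate 4, to 1.57, and with no fraction minimum it was 0.5. Fisher's exact test of presence or absence found 0 of 12 called variants past an adjusted or an unadjusted p of 0.05 for KC_KO against KC_WT, and likewise 0 of 12 for liver against culture. Since each variant was called in 11, 3 or 1 libraries, none could reach 0.05 at 4 against 4, nor could those called only in liver at 8 against 3. Over all 31 listed variants, liver against culture gave 3 at an unadjusted p under 0.05 and 0 after adjustment.

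Sharing separated the 12 called variants into 5 present in all libraries, 5 called in 1 library and 2 called in 3 liver libraries. No variant was called in 2 or more libraries of 1 liver group and in none of the other. The pair called in 3 liver libraries and in no cultured library was Kdm6a L643Ffs*50 and Ncor1 S51N. Kdm6a L643Ffs*50, a HaplotypeCaller call, is an insertion of TTTTT annotated as a frameshift in a histone demethylase gene. It lay at chromosome X, positions 18254006 to 18254007, in exon 17 of 29. It made up 9.78% of reads in KC_KO replicate 3 (interval 6.23 to 14.4), 8.26% in KC_KO replicate 4 (interval 4.97 to 12.7) and 8.61% in KC_WT replicate 4 (interval 5.18 to 13.3). Tail DNA had 2 of 434 reads there (0.461%), the highest tail fraction of the 31 listed variants. Ncor1 S51N, in a nuclear receptor corepressor gene at chromosome 11, position 62433656, in exon 3 of 46, made up 20.4% of reads in KC_KO replicate 4 (interval 14.1 to 28.0), 10.9% in KC_WT replicate 4 and 6.90% in KC_WT replicate 3. Tail DNA had 0 of 137 reads there, which allows a share of up to 2.19%.

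The 5 private calls were 4 in KC_KO replicate 4 and 1 in KC_WT replicate 4; apart from Sf3b1, their names were taken after their values were seen. KC_KO replicate 4 carried a 46-base insertion in the splicing factor gene Sf3b1 at chromosome 1, positions 55016883 to 55016884, in 23 of 120 reads (19.2%, interval 12.6 to 27.4). It also carried a 49-base insertion in Ncor1 at chromosome 11, positions 62410933 to 62410934, in 50 of 618 reads (8.09%, interval 6.06 to 10.5). Both insertions were annotated at a splice region and as frameshifts with a premature stop, D66Ifs*12 in Sf3b1 and Q208Rfs*11 in Ncor1. The other private calls there were an in-frame deletion, G457_G460del, in the histone methyltransferase gene Setd1a (17.8%, interval 12.8 to 23.7) and L169P in Gli1, a transcription factor of Hedgehog signalling (11.2%, interval 7.94 to 15.3). The former lay at chromosome 7, positions 127785318 to 127785329, in exon 7 of 19, and the latter at chromosome 10, position 127337050, in exon 6 of 13. Gli1 L169P was private only by the call minimum. It was also listed below that minimum in KC_KO replicates 1 and 2 and KC_WT replicates 3 and 4, at 1.16% to 4.14%. KC_WT replicate 4 carried E114del in the ubiquitin ligase gene Traf7 in 7 of 75 reads (9.33%, interval 3.84 to 18.3), at chromosome 17, positions 24514716 to 24514718, in exon 5 of 21. Like Kdm6a L643Ffs*50, the Sf3b1 and Ncor1 insertions and the Setd1a and Traf7 deletions were HaplotypeCaller calls. That caller gave 4 rows in KC_KO replicate 4, 2 in KC_WT replicate 4, 1 in KC_KO replicate 3 and none in the other libraries. Private calls per library averaged 1.0 ± 2.0 in KC_KO (SD, n = 4) and 0.25 ± 0.50 in KC_WT (SD, n = 4; exact two-sided permutation p = 1). Without KC_KO replicate 4 that difference was -0.25. With presence taken at 2 or more variant reads, which every listed row met, it was 2 (exact permutation p = 0.0857).

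Calls absent from cultured cells numbered 0, 0, 1 and 6 in KC_KO libraries and 0, 0, 1 and 3 in KC_WT libraries, means of 1.75 ± 2.87 and 1.0 ± 1.41 (SD, n = 4 each; exact two-sided permutation p = 0.886). The difference of 0.75 became -0.667 without KC_KO replicate 4. Cultured libraries called only the 5 shared variants, so these counts are the calls per library less 5. The comparison thus repeats that of calls per library and is no separate result. The 2 libraries with the most such calls, KC_KO replicate 4 and KC_WT replicate 4, also had the highest reference shares at the Trp53 R172H site, 22.4% (interval 18.8 to 26.3) and 8.61% (interval 6.55 to 11.1). In the other 6 liver libraries that share was 1.6% to 4.52%. Gli1 L169P and Ncor1 S51N were listed in 5 and 4 liver libraries, some of them below the call minimum, and their fractions were highest in the same pair of libraries.

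**Figure D2:**
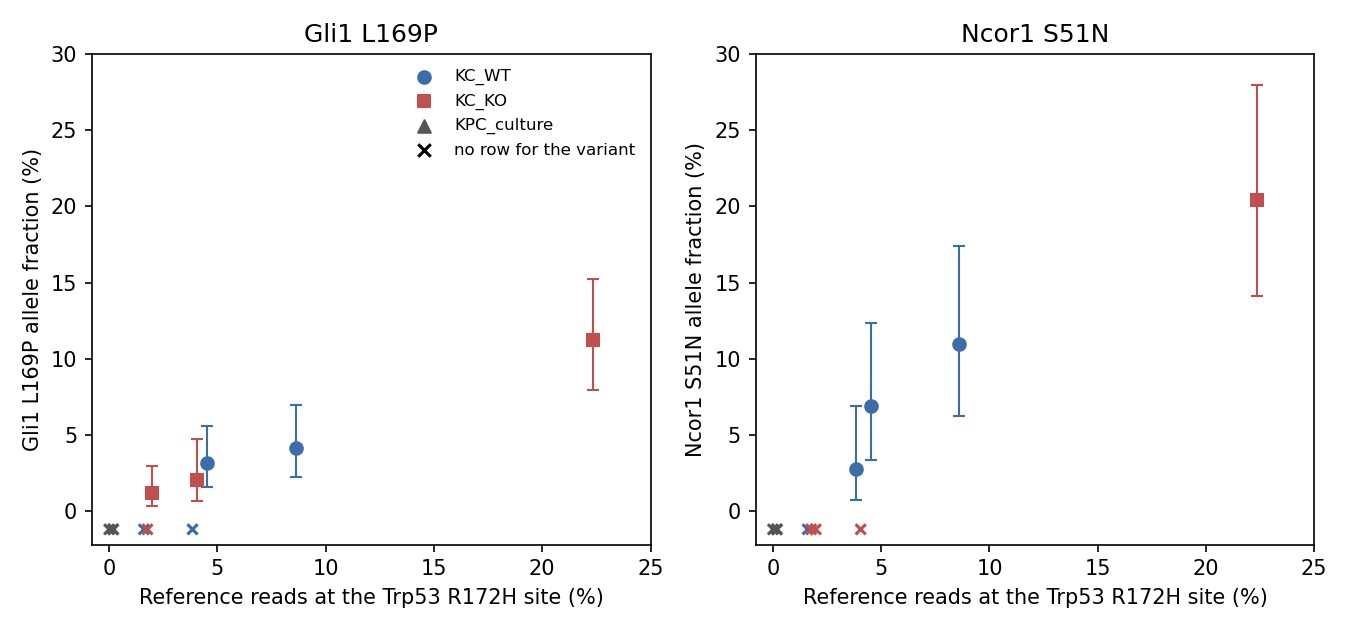
Allele fraction in percent of Gli1 L169P (left) and Ncor1 S51N (right) against the percentage of reference reads at the Trp53 R172H site in the same library, with exact 95% intervals as error bars. Crosses below 0 mark libraries with no row for the variant, which have no fraction. KC_KO replicate 4 lies farthest right, at 22.4%, with 11.2% for Gli1 and 20.4% for Ncor1.

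Base substitutions among the 7 called single base variants fell into 3 of 6 classes: 3 C>T, 3 T>C and 1 T>A. The C>T class includes the engineered alleles Kras G12D and Trp53 R172H. Since 5 of the 7 were called in every library, shares could differ between libraries only through Ncor1 S51N and Gli1 L169P. The comparison is therefore not a test of mutational processes. C>T made up 40.7% ± 1.43 of single base calls in KC_KO (SD, n = 4) and 45.0% ± 5.77 in KC_WT (SD, n = 4), and T>C 40.7% ± 1.43 and 36.7% ± 3.85. Neither difference passed the test (exact two-sided permutation p = 0.429 and 0.286). KC_KO minus KC_WT for T>C was 9.80 points with no fraction minimum and 10.4 with all listed rows (exact permutation p = 0.0857 for each). For C>T it was -1.95 and -3.94 points (exact permutation p = 0.657 and 0.371). None of the 6 classes passed an unadjusted or adjusted p of 0.05 (adjusted p = 1 for each). Among all 26 listed single base variants, 9 were C>T, 7 T>C, 4 C>A, 4 C>G and 2 T>A.

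Called variants reached 3 of the 8 gene lists fixed before the data were examined. Of 23 pancreatic cancer driver genes, 4 were called: Kras and Trp53 in all 11 libraries, Kdm6a in 3 and Sf3b1 in 1. Calls in that list averaged 2.75 ± 0.957 per library in KC_KO and 2.25 ± 0.50 in KC_WT (SD, n = 4 each; exact permutation p = 0.714). Of 34 chromatin regulator genes, 3 were called, Tet2, Ncor1 and Kdm6a, with 2.00 ± 1.41 calls in KC_KO and 1.75 ± 0.957 in KC_WT (SD, n = 4 each; exact permutation p = 1). KC_KO replicate 4 was the only KC_KO library with calls in Sf3b1 and Ncor1, so the KC_KO means of both lists lean on that library. Of 28 RAS, MAPK and PI3K signalling genes, Erbb3 alone was called, once in each library. DNA repair genes had 0 calls and 1 listed gene, Chek1; cell cycle and apoptosis genes had 0 calls and 1 listed gene, Trp53bp1. The lists for antigen presentation, interferon and immune recognition, for WNT, NOTCH, TGF-beta and adhesion, and for macrophage and Kupffer cell factors had 0 listed variants. Under exact permutation, 0 of 8 lists passed before or after adjustment. Adjusted over the list alone, Trp53 R172H in liver against culture was 1 of 2 tested driver variants to pass in limma (adjusted p = 0.000755), and 0 of 2 passed between KC_KO and KC_WT. Both tested driver variants are the engineered alleles. The pass is the limma result given above, adjusted over fewer variants, and no separate result. As given there, the Trp53 call was lost on the arcsine scale, in a quasi-binomial model and in exact permutation of the fractions.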

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

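The tests of the Gli1, Ncor1 and Sf3b1 patterns were chosen after those results were seen. In a group of 4, chance alone marks about 1 in 20 comparisons as having a library far from the others; 24 were tested. KC_KO replicate 4 stood apart from the other 3 KC_KO libraries in its 11 calls (others 5 to 6) and its 4 private calls (others 0). Its 6 calls absent from culture (others 0 to 1) are the same reading as its 11 calls, less the 5 shared variants. KC_KO replicate 4 also stood apart in a reference share of 22.4% at the Trp53 R172H site (others 1.76% to 4.05%), which is the same reading as its Trp53 R172H fraction of 77.4% (others 95.7% to 98.0%). KC_WT replicate 4 had 1 private call where the others had 0. Any count above 0 beside 3 libraries at 0 is marked in this way, so the private calls of both libraries carry no weight as outliers, and the rate of 1 in 20 does not hold for such tied counts. The Kras G12D fraction of KC_KO replicate 4 was 37.8%, against 52.7% ± 3.01 over the other liver libraries (SD, n = 7). Dilution by the reference share at the Trp53 R172H site would bring that mean to 40.9%, inside the interval of 31.7 to 44.2. Divided by the Trp53 R172H fraction, the Kras G12D value was 48.8%, against 50.0% to 58.7% in the others. The other shared variants were mixed. Erbb3 S844C and Tet2 H801R in KC_KO replicate 4, at 15.7% and 12.1%, were the lowest of the liver libraries. Fgfr2 F664L showed no clear fall there, with an interval of 16.1 to 24.3, against a liver mean of 20.6%. Divided by the Trp53 R172H fraction, Fgfr2 in that library was 25.8%, the highest in liver. Diluted values were not computed for these variants, so the match to dilution covers Kras alone.

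Reads of Gli1 L169P and Ncor1 S51N, both without a row in cultured cells, varied between liver libraries. A single fraction for all libraries that list the variant was rejected for both where counting error is the only error (multinomial simulation gave 1e-05, the smallest its 100000 draws can give). Libraries also differ by more than counting error: chi-square over its degrees of freedom was 12.1 for Gli1 and 8.93 for Ncor1, against 3.75 for Tet2 H801R over the 8 liver libraries, the widest of the shared variants apart from Trp53, and an F test against that spread passed for neither (0.0846 and 0.155). Depth at the Ncor1 site was 137 to 145 reads in the libraries that list it, while the fraction ran from 2.76% to 20.4%. At the Gli1 site KC_KO replicate 4 and KC_WT replicate 4 had 312 and 314 reads but fractions of 11.2% and 4.14%. These values argue against unequal depth in the libraries they cover. Spread between libraries beyond counting error stays open, but the F test decides little. It had 4 and 3 degrees of freedom for Gli1 and Ncor1 and was made only against the widest spread, that of Tet2. The chi-square over its degrees of freedom was 3.55 for Kras G12D, 1.72 for Erbb3 S844C and 1.03 for Fgfr2 F664L. DNA of host cells among the sorted cells stays open too, as a hypothesis formed on these reads: over the libraries that list them, proportionality to depth times the reference share was not rejected (the same simulation gave 0.368 for the lower of the pair). A tumour subclone unrelated to that share also stays open. A permutation of the fractions against the share over the 8 liver libraries (exact one-sided p = 9.92e-05) decides nothing here, since the variants were picked for this relation and unlisted libraries entered as 0. Host DNA would need the host of each library to carry the alleles listed there. Tail DNA had 0 of 412 reads at the Gli1 site and 0 of 137 at the Ncor1 site. That tail DNA came from a single mouse labelled with neither host group, so its reads do not show what the hosts carried. The listing is uneven: KC_WT replicate 1, at a reference share of 3.85%, lists Ncor1 but no Gli1 row. KC_KO replicate 2, at 4.05%, lists Gli1 but no Ncor1 row. This unevenness counts neither way, since hosts may differ between libraries and a missing row does not show absence.

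The Sf3b1 and Ncor1 insertions of KC_KO replicate 4 sit between the last base of an intron and the first base of an exon. On the coding strand they read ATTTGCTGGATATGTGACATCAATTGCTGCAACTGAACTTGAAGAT and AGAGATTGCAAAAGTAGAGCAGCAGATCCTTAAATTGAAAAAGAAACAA. Read in frame from the second base, each encodes the 11 listed residues that precede it (11 of 11 for both, VTSIAATELED and EQQILKLKKKQ), the end of the exon before. Reads from a spliced copy of the transcript, such as complementary DNA or a processed pseudogene, may therefore be a source of both. The genome sequence was not used here, and no biological explanation was tested.

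Of the variants never called, 5 were listed in at least 3 libraries. Rows are listed because variant reads were found, so their fractions were not tested against tail DNA. Dicer1 P1591H was listed in 10 libraries at 1.64% (132 of 8064 reads, against 1 of 818 in tail DNA). Trp53 G371D was listed in 3 liver libraries at 1.79% (39 of 2175 reads, against 1 of 756). Il7r P406A was listed in the 3 cultured libraries at 2.61% (51 of 1953 reads, against 0 of 611). Nipbl Y1606H was listed in the 3 cultured libraries and KC_KO replicate 1 at 3.21% (65 of 2026 reads, against 0 of 446). Suz12 A66G was listed in the 3 cultured libraries and KC_WT replicate 3 at 1.22% (34 of 2781 reads, against 1 of 635). Libraries without a row do not enter these fractions.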

How the results depend on the processing

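Use of all listed rows, fractions divided by that of Trp53 R172H, rank permutation, the sign-flip test of engineered alleles and all alternatives of gene lists and presence were chosen after seeing the data. Trp53 R172H in liver against culture was the only call, 1 of 5 variants. It was lost, giving 0, with a quasi-binomial model (log2 odds -5.76, against -4.61 in the main fit), limma on the arcsine scale and exact permutation. Rank permutation also gave 0, but there a lone variant cannot fall below an adjusted p of 0.0606, the value Trp53 R172H had (exact p = 0.0121), so it counts neither way. Divided by the Trp53 R172H fraction, 2 of 4 variants passed in liver against culture, Erbb3 S844C (log2 0.24) and Tet2 H801R (log2 0.27, adjusted p = 0.0485 for both in limma). Division by a fraction that was lower in liver raised all 4 variants. The SE was 0.0999 for each of them on log2 of the divided fraction, against 0.125 for Erbb3 and 0.139 for Tet2 in the undivided log2 odds. Fractions and odds are unlike measures, so these SEs cannot be compared directly. The Erbb3 and Tet2 calls cannot be told apart from an effect of the scaling or of the change of measure, neither of which was tested. They are not taken as changes of either variant. With each library left out in turn the count without division stayed at 1, with Trp53 log2 odds of -4.92 to -4.03. Of 100 splits of the 11 libraries into 8 and 3, 6 gave as many calls, so chance is not excluded (real 1, highest other 1). For KC_KO against KC_WT the real count was 0, which all 35 of 35 splits reach by construction, so the splits test nothing there (highest other 1).

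No other comparison passed its threshold under any alternative, but directions turned when 1 library was left out. KC_KO minus KC_WT ranged from -0.667 to 1.42 for calls, protein-altering calls and calls absent from culture, from -0.25 to 1.08 for private calls and from -0.205 to 1.69 points for the median fraction. The ranges were -3.87 to 2.26 points for Kras G12D and -4.90 to 1.97 for Trp53 R172H. In log2 odds they were -0.24 to 0.12 for Kras, -0.60 to 0.71 for Trp53 and -0.092 to 0.084 for Fgfr2, and for Kras in liver against culture -0.070 to 0.14. The median fraction difference was -0.261 with all listed rows, and Fgfr2 was -0.00728 in the quasi-binomial model. Private calls differed by 2 with all listed rows and with presence at 2 or more variant reads (exact permutation p = 0.0857). These 2 settings keep the same rows. The tail filter and, for shared variants, the depth and mean fraction filters removed nothing, so they say nothing about stability.

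In a check of pairing over 5 variants, correlations of same-numbered KC_WT and KC_KO libraries were -0.115, -0.555 and -0.298 for replicates 1 to 3. For replicate 4 the value was 0.761, and it alone correlated best with its own number. These are not correlations of the fractions themselves, and the scale used is not given here. In all libraries the Trp53 R172H fraction was highest, then that of Kras G12D, with the rest far lower. Replicate 4 also had the most calls and the highest Trp53 reference share in both groups. The replicate numbers were not taken to pair the libraries, since not every pair correlated on that scale and the labels name no pairing. The replicate block left 0 limma calls between KC_KO and KC_WT and 1 in liver against culture (log2 odds -3.98), and the difference in calls at 0.75 (exact sign-flip permutation p = 1, where 0.125 is the smallest possible). Depth limits fractions near 1%, which rest on as few as 4 reads.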

Other observations

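Among variants without any row in cultured cells, 20 were listed in liver libraries, over 35 rows, of which 9 were in KC_KO replicate 4. In KC_KO replicate 3, Kdm6a L643Ffs*50 stood at 9.78% (interval 6.23 to 14.4) against a reference share of 1.76% at the Trp53 R172H site (interval 0.810 to 3.32). It was picked from these rows after the data were seen, and the intervals cover counting error only. In KC_KO replicate 4 and KC_WT replicate 4 the Kdm6a insertion fraction was 8.26% against 22.4% and 8.61% against 8.61%. Ikzf3 A236E, in a lymphoid transcription factor gene, was listed in KC_WT replicates 3 and 4 at 2.95% and 3.88%.

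Il7r, which encodes the interleukin-7 receptor, and Nipbl, which encodes a cohesin loading factor, carried variants listed mainly in cultured cells. Il7r P406A at chromosome 15, position 9508019, had a row in 3 of 3 cultured and 0 of 8 liver libraries (Fisher's exact test p = 0.00606, adjusted p = 0.188 over 31 variants). Nipbl Y1606H at chromosome 15, position 8327085, had a row in 3 of 3 cultured and 1 of 8 liver libraries (exact p = 0.0242, adjusted p = 0.251), as did Suz12 A66G. At the cultured fraction, and with each liver library's relative depth and Trp53 reference share, 11.6 to 19.3 variant reads were computed for Il7r P406A, 13.7 to 22.7 for Nipbl Y1606H and 5.93 to 9.85 for Suz12 A66G. The rule for listing a row is not given, so the missing rows do not show that any of these variants was absent from liver; for Suz12 the expected reads were few. KC_KO replicate 1 listed 5 variant reads of 491 for Nipbl Y1606H (1.02%), against 3.25% to 4.93% in cultured cells.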
